A study of Mus musculus with 4 samples.

How the data were processed

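Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags DNA that is not packed in nucleosomes. The cells were naive CD4 T cells from the spleen and lymph nodes of wild-type mice (2 libraries) and of mice labelled as Ddx55 knockout (2 libraries). Per the labels' protocols, nuclei were released with a mild detergent buffer, libraries were made with a transposase kit, and size-selected fragments were sequenced as read pairs. The submitters' processing notes name fastp 0.12.4, Bowtie2 2.5.08, SAMtools 1.15.1 and MACS3 3.0.0b1, and the mouse build mm10. The role and settings of each tool, the handling of duplicate reads and of the offset of transposase cuts, the peak threshold and the use of a list of excluded regions are not given in the sources used here.

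The deposited data analysed here are 1 list of accessible regions for the whole series, cited in the labels of all 4 libraries. It has 3 columns (sequence name, start and end) and no header. It carries no read count, score, library or genotype. How the authors joined the peaks of the 4 libraries is not given in the sources used here; the regions do not overlap one another, and the smallest gap between neighbours is 1 bp. Depth per library is therefore unknown, and no standard deviation between libraries can be given. Intervals around shares are 95% exact (Clopper-Pearson) binomial intervals. They cover counting error over genes or regions only, and neighbouring regions are not independent.

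Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names. Region coordinates were converted from BED to 1-based positions. The scaffold names in the list are those of this assembly, and the last region and the last annotated gene lie close together on each assembled chromosome. The table gives the start and end of each gene and its kind, without strand, transcripts or sequence. Promoters had been planned as windows around annotated transcription start sites. Without strand, a gene was instead counted as accessible at an end when a region overlapped, by at least 1 bp, the 1 kb on either side of either annotated end. This counts some 3' ends, and it misses start sites that lie inside a longer gene model. The planned comparison of the knockout with the wild type needed values per library or genotype and was not analysed here. The 28 sequence motifs planned and the matching of genes on promoter CpG content needed a genome sequence and were not analysed here; random gene lists were matched on gene length in their place.

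The 16 gene lists were written before the data were examined. Of their 373 entries, 371 matched a protein-coding gene, 1 of them through an older symbol; Mx1 and Mx2 are pseudogenes in the table and were left out. The 371 entries are 368 distinct genes, with Eomes, Gzma and Prf1 in more than 1 list. The background was the 21887 protein-coding genes on chromosomes 1 to 19, X and Y. The share of each list with a region at a gene end was compared with that of all other genes by a two-sided Fisher's exact test. The mean number of regions in the gene body and 10 kb on either side was compared with 10000 random lists, drawn with replacement from the same 10 bins of gene length, by a two-sided permutation test. Both families were adjusted over the 16 lists by the Benjamini-Hochberg method, with a threshold of 0.05. The position of regions relative to genes was compared with 100 placements of regions of the same widths at random between the first and last region of each chromosome; assembly gaps were not masked. The smallest two-sided p that the random lists can give is 0.0002, and that of the placements is 0.0198.

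The named genes followed a rule: Ddx55; from each list the 3 members with the most regions (ties by alphabet) and up to 2 members without a region at a gene end (by alphabet); the 10 protein-coding genes with the most regions; and the 5 widest regions. Some genes that the rule selects are not reported here. Other genes named were chosen after their values were seen, as examples. The list tests were tested on simulated data: regions were placed at random, 160 of 200 chosen genes were given a region at an end, and all 200 were given 3 regions in a flank. Both tests called 10 of 10 lists of 20 such genes. Of 200 lists of other genes in the same simulation, Fisher's exact test called 2.5% and the permutation test called 6% at an unadjusted p under 0.05. With random placement alone, 17 of the 200 chosen genes had a region at an end, whereas 52.6% of genes had one in the data. The simulated contrast was therefore easier to detect, and the simulation does not show the power or the false call rate on these lists. The alternatives tried were other window and flank sizes, the middle of the region in place of any overlap, wider regions only, merging of neighbouring regions, other sets of chromosomes, genes or list members, and matched lists in place of Fisher's exact test. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; plots were drawn with matplotlib 3.10.9.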

Results

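Ddx55 encodes a DEAD-box RNA helicase that takes part in making the large ribosomal subunit. The series set out to compare open chromatin in naive CD4 T cells, the resting helper T cells that have not met antigen, between wild-type and Ddx55-knockout mice. ATAC-seq was performed on 4 libraries, 2 from each genotype; the labels do not say whether the replicates came from separate animals. The data analysed here are the joint list of accessible regions for all 4 libraries, on mouse build mm10. The list gives the position of each region and no value per library or genotype, so the difference between genotypes was not analysed here, and all values below describe the regions of both genotypes together.

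The list held 64525 regions that covered 26.9 Mb. Region width had a median of 294 bp, with lower and upper quartiles of 207 and 536 bp and a range from 75 to 5833 bp. Of the regions, 64233 lay on assembled chromosomes, 292 on scaffolds and 0 on the mitochondrial sequence. The median gap between neighbouring regions was 18.5 kb. Across the 19 autosomes the density was 25.8 ± 2.32 regions per Mb (mean ± SD over chromosomes), from 21.7 on chromosome 14 to 31.8 on chromosome 11. Chromosome X carried 878 regions, or 5.14 per Mb, 4.22 times below the lowest autosome. A region lay at a gene end for 33.2% of the X-linked protein-coding genes and 54.1% of the autosomal ones (odds ratio 0.421, 95% interval 0.368 to 0.483, two-sided Fisher's exact test p = 2.5e-37). Chromosome Y carried 54 regions, which included gene ends of Kdm5d, Eif2s3y, Uty and Ddx3y.

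**Figure D1:**
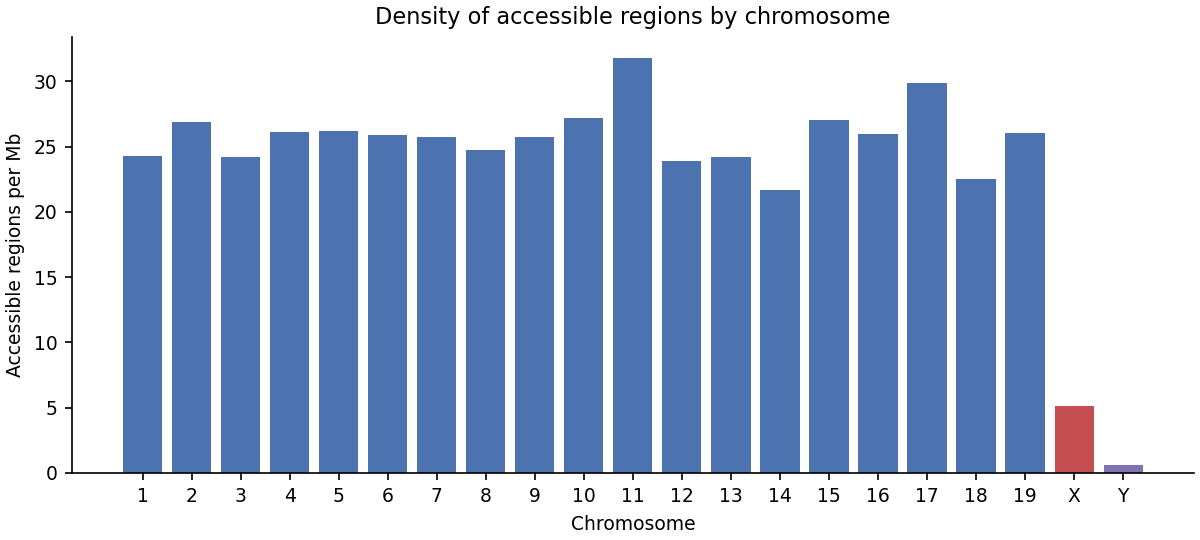
Accessible regions per Mb (vertical axis, linear from 0) on each assembled chromosome (horizontal axis), counted up to the last region of the chromosome. The autosomes (blue) lie between 21.7 and 31.8 regions per Mb, X (red) at 5.14 and Y (purple) lowest.

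The Ddx55 gene (chromosome 5, 124552832 to 124569660, gene ID 67848) had a single region at its ends. This region, 842 bp wide, spanned 124552594 to 124553435 and overlapped the lower-coordinate end of the gene. No other region overlapped the gene. The next region, 1144 bp wide at 124578875 to 124580018, began 9.21 kb past the gene and overlapped ends of both Eif2b1, which encodes a subunit of a translation initiation factor, and Gtf2h3, which encodes a subunit of a general transcription factor. On the other side, a region of 253 bp lay at an end of Tmed2. The list pools both genotypes, so it does not show which libraries gave the region at Ddx55.

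Accessible regions were concentrated at the ends of protein-coding genes. Of the 64233 regions on assembled chromosomes, 11867 (18.5%, 95% exact interval 18.2 to 18.8%) lay within 1 kb of a gene end, against 3.72% ± 0.0811 (SD) over 100 random placements, a ratio of 4.97 (two-sided permutation p = 0.0198, the smallest the placements can give). A further 24564 regions (38.2%) lay inside genes away from their ends, close to the 38.9% ± 0.196 of the placements, although below all of them. The 27802 regions outside genes (43.3%) were fewer than the 57.4% ± 0.198 placed there. Regions at gene ends were wider, with a median of 715 bp against 277 bp inside genes and 251 bp outside. By gene, 11515 of the 21887 protein-coding genes (52.6%) had a region at either end, against 11.1% ± 0.235 in the placements, and 1296 genes (5.92%) had one at both ends. Because the gene table carries no strand, these shares do not separate start sites from 3' ends.

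The share at gene ends rose with region width. In the narrowest class of regions, 75 to 207 bp, 4.98% lay at a gene end (95% exact interval 4.65 to 5.33%), against 3.3% ± 0.141 in the placements. The share was 6.41% for widths of 208 to 294 bp and 13.4% for 295 to 535 bp. In the widest class, 536 bp and above, 49.2% of 16033 regions lay at a gene end (48.4 to 50.0%), against 4.44% ± 0.171 in the placements.

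**Figure D2:**
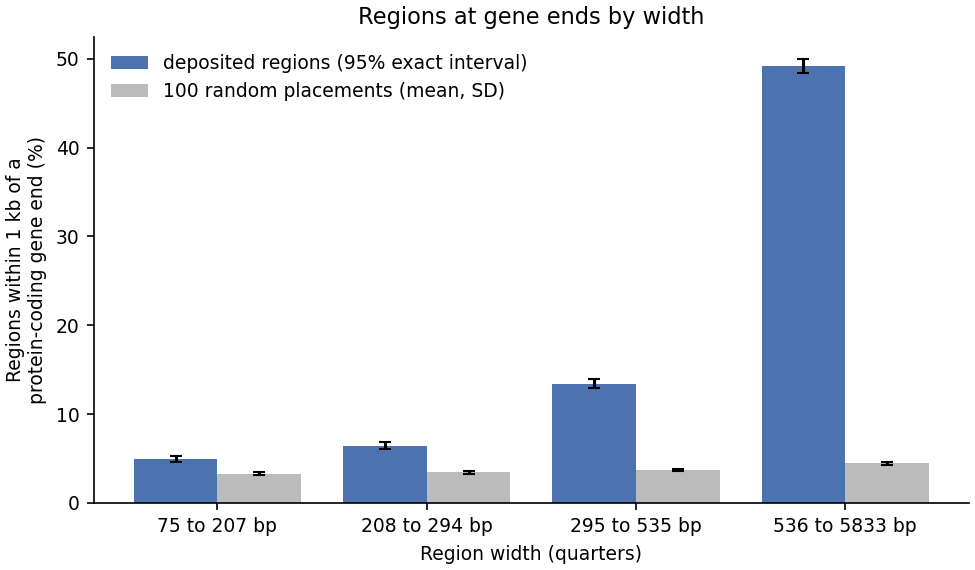
Percent of regions within 1 kb of a protein-coding gene end (vertical axis, linear from 0) in 4 classes of region width in bp (horizontal axis), for the deposited regions (blue, 95% exact interval) and 100 random placements (grey, mean and SD). The share climbs from 4.98% in the narrowest class to 49.2% in the widest, while the placements stay between 3.3 and 4.44%.

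Genes of naive T cell identity, ribosomes and the cell cycle had a region at a gene end more often than other genes. Of the 16 gene lists, 7 had a higher share with a region at a gene end than the other protein-coding genes, 3 had a lower share and 6 did not pass the test (two-sided Fisher's exact test, Benjamini-Hochberg adjustment over the lists). Of 32 genes of naive T cell identity, which encode the T cell receptor complex, co-receptors, their kinases and lineage regulators, 30 had such a region (93.8%, 95% exact interval 79.2 to 99.2%, against 52.6% of other genes; exact-test adjusted p = 3.25e-06). They included Cd3d, Cd3e and Cd3g of the receptor complex, Cd4, the kinases Lck and Zap70, the transcription factors Tcf7, Lef1 and Bcl11b, and the chemokine receptor Ccr7. The 2 exceptions were Ets1 and Gata3, both lineage transcription factors, which had 20 and 6 regions inside the gene. Promoter CpG content was not matched for this list, so its part in the high share was not tested.

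The lists on ribosomes and on cell division had similarly high shares. Of 48 ribosome biogenesis factors, which include Ddx55, 45 had a region at a gene end (93.8%, exact-test adjusted p = 4.96e-09). The 3 without one were the helicase Ddx56, Nat10, an RNA acetyltransferase, and Noc2l, and each had regions inside the gene or within 10 kb. Of 40 ribosomal protein genes 39 had one (97.5%, exact-test adjusted p = 4.96e-09). The exception, Rps2, had 1 region inside the gene. Of 31 cell cycle genes 30 had one (96.8%, exact-test adjusted p = 6.24e-07), including Mki67, Top2a and Cdk1; the exception was Ccnd3, the gene of cyclin D3, with 10 regions inside it. Many of these genes are used in most cell types, and promoter CpG content, on which such genes differ from others, was not matched.

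Lists of inducible genes also had a region at a gene end more often than other genes. Promoter CpG content was not matched for these lists either, and the regions pool both genotypes. Of 22 immediate early and T cell activation genes 19 had a region at a gene end (86.4%, exact-test adjusted p = 0.00391), including Fos, Jun, Nr4a1 and Cd69. The 3 exceptions were Egr2, Nfatc1 and the cytokine gene Il2, with 2, 10 and 0 regions inside the gene. Of 20 p53 target genes 18 had one (90.0%, exact-test adjusted p = 0.00123), among them Mdm2 and Bax. Cdkn1a, which encodes a cell cycle inhibitor, and the X-linked Eda2r did not, with 2 and 0 regions inside the gene. Of 24 interferon-induced genes 20 had one (83.3%, exact-test adjusted p = 0.00577), including Irf7 and Ifit3, while Eif2ak2, Ifi44, Isg15 and Oas1a did not. The interferon result was lost when a region anywhere in the gene counted (83.3% against 67.6% of other genes, exact-test adjusted p = 0.169).

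Genes of other tissues and of B cells were less often accessible at their ends. Promoter CpG content was not matched for these lists either, so its part in the lower shares was not tested. Of 22 liver genes 3 had a region there (13.6%, 95% exact interval 2.91 to 34.9%, exact-test adjusted p = 0.000972); Alb, which encodes serum albumin, and Ahsg were among the 19 without one. Of 24 neuronal genes 4 had one (16.7%, exact-test adjusted p = 0.000972), and Camk2a and Dlx1 had none. Of 18 B cell genes 4 had one (22.2%, 6.41 to 47.6%, exact-test adjusted p = 0.0251), and Cd79a, Ms4a1, Pax5 and Blk had none at an end. The B cell result was lost with windows of 2 kb, where 44.4% of the list against 57.8% of other genes had a region (exact-test adjusted p = 0.418), and the 3 lower shares were all lost when a region anywhere in the gene counted.

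The lists of other blood lineages and of specialised T cells did not pass this test. The shares were 75% of 12 regulatory T cell genes (exact-test adjusted p = 0.203), 57.7% of 26 effector helper genes (exact-test adjusted p = 0.742) and 40.0% of 10 CD8 T cell genes (exact-test adjusted p = 0.609). They were 35.0% of 20 myeloid genes (exact-test adjusted p = 0.179), 33.3% of 12 red cell and platelet genes (exact-test adjusted p = 0.306) and 50.0% of 10 natural killer cell genes (exact-test adjusted p = 1). Genes without a region at an end included the regulatory T cell factors Foxp3, which is X-linked, and Ikzf4, the chemokine receptors Ccr4 and Ccr6, and Cd8a and Gzma of cytotoxic cells. They also included Adgre1 and Cd68 of macrophages, Klrb1c of natural killer cells, and Alas2 and Gata1 of red cells, both X-linked. The intervals of these small lists were wide, for example 12.2 to 73.8% for the CD8 T cell list. At 500 bp on either side the share of red cell and platelet genes fell below that of other genes (8.33%, exact-test adjusted p = 0.0104).

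**Figure D3:**
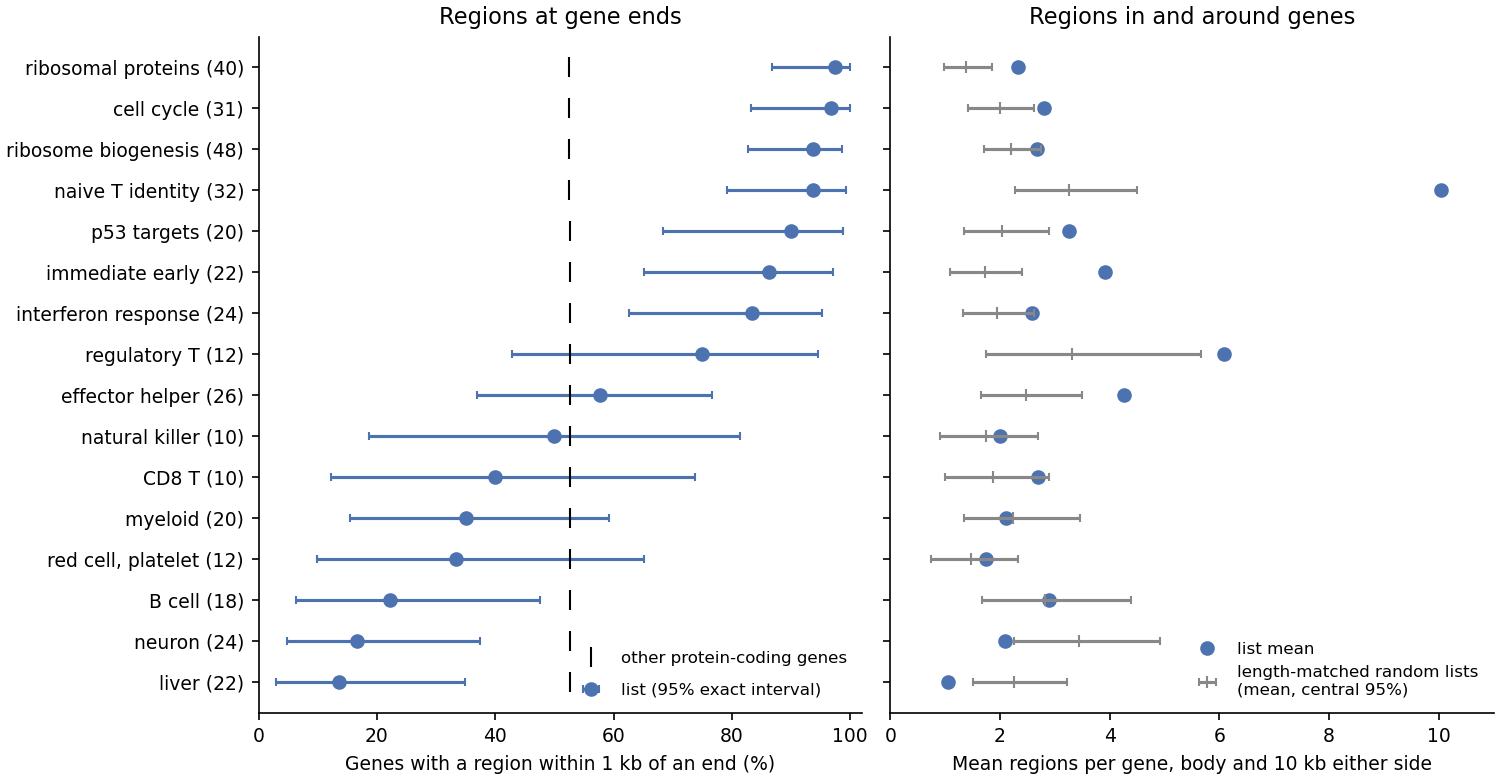
Left, percent of each gene list with a region within 1 kb of a gene end (points, 95% exact interval) and the percent of all other protein-coding genes (vertical ticks); right, mean number of regions per gene in the body and 10 kb on either side (points) and in 10000 length-matched random lists (grey, mean and central 95%). The number of genes in each list is in brackets. Naive T cell identity genes stand at 93.8% on the left and at 10.0 regions per gene on the right, beyond their matched lists.

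Of the 16 lists, 7 had more regions in and around their genes than length-matched random lists, 2 had fewer and 7 did not pass the test. Naive T cell identity genes had 10.0 ± 9.68 regions per gene (mean ± SD over 32 genes) in the body and 10 kb on either side, 3.08 times the 3.26 of length-matched random lists (permutation adjusted p = 0.00107). Foxp1, a transcription factor that keeps naive T cells quiescent, had the most at 53 regions, followed by Runx1 with 25 and Ets1 with 22, where genes in the same length bin averaged 6.9. That bin is wide, with genes such as Cps1 (109 kb) and Ptprd (2270.5 kb), so Foxp1 (597 kb) was matched only loosely on length. Without Foxp1 the list mean was 8.65. Immediate early genes had 3.91 ± 2.47 regions per gene, 2.27 times the matched lists (permutation adjusted p = 0.00107), led by Nfatc1 with 12 and by Ier2, Junb, Nr4a1 and Nr4a3 with 6 each.

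Effector helper and regulatory T cell genes, whose shares at gene ends did not pass the test, had more regions per gene than length-matched lists. The 26 effector helper genes had 4.27 ± 5.27 regions per gene, 1.72 times the matched lists (permutation adjusted p = 0.0102). Rora, which encodes a nuclear receptor of the Th17 lineage, had 24, Stat4 had 14 and Il12rb2 had 9, the latter pair belonging to interleukin-12 signalling. Rora is 735 kb long and falls in the wide bin of the longest genes, so its count was matched only loosely on length. The cytokine genes Ifng, Il5 and Il17f had 0 regions, Il4, Il10 and Il17a had 1 each, and Il13 and Il21 had 2 each. The 12 regulatory T cell genes had 6.08 ± 3.23 regions per gene, 1.84 times the matched lists (permutation adjusted p = 0.0476), with 13 at Il2ra, 10 at Ikzf2 and 9 at Entpd1. Neither passed when the member with the most regions was left out: the ratio was 1.51 without Rora (permutation adjusted p = 0.0533) and 1.62 without Il2ra (permutation adjusted p = 0.132). The regulatory T cell result also missed the threshold in the gene body alone (ratio 1.52, permutation adjusted p = 0.268), without overlapping members (1.8, permutation adjusted p = 0.0636) and without regions at gene ends (1.84, permutation adjusted p = 0.193).

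Ribosomal protein genes had 2.33 ± 0.917 regions per gene against 1.38 in the matched lists (permutation adjusted p = 0.00107), with 4 at each of Rpl19 and Rpl38. The p53 targets had 3.25 ± 2.15 against 2.04 (permutation adjusted p = 0.0245), led by Sesn1 with 10, Aen with 6, and Btg2 and Polk with 5 each. Cell cycle genes had 2.81 ± 2.34 against 1.99 (permutation adjusted p = 0.0338), led by Ccnd3 with 12, E2f2 with 8 and Aurkb with 6. The p53 result missed the threshold without Sesn1 (ratio 1.48 against 1.59 with it, permutation adjusted p = 0.0672) and the cell cycle result without Ccnd3 (1.29 against 1.41, permutation adjusted p = 0.126). With regions at gene ends left out, 3 of the 7 lists with higher counts still passed: naive T cell identity (8.31 regions per gene against 2.29, permutation adjusted p = 0.0032), immediate early (2.32 against 0.791, permutation adjusted p = 0.0032) and effector helper (3.54 against 1.51, permutation adjusted p = 0.0107). The p53 list then missed the threshold at a ratio of 1.82 (permutation adjusted p = 0.0646), the ribosomal protein list at 1.47 (permutation adjusted p = 0.245) and the cell cycle list at 1.34 (permutation adjusted p = 0.27).

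Liver genes had 1.05 ± 0.999 regions per gene, 0.463 times the matched lists (permutation adjusted p = 0.0064), with 2 each at Apoa2 and Fgb. Neuronal genes had 2.08 ± 2.7, 0.605 times the matched lists (permutation adjusted p = 0.0416); the long genes Syt1, Rbfox3 and Grin2b had 9, 8 and 7. These 2 lower means were not called with regions at gene ends left out (ratios 0.614 and 0.731, permutation adjusted p = 0.27 and 0.377). The other 7 lists did not pass. B cell genes had 2.89 regions per gene against 2.83 in matched lists (permutation adjusted p = 0.916), with 11 at Bank1, 6 at Ebf1 and 5 at Pax5. Myeloid genes had 2.1 against 2.23 (permutation adjusted p = 0.916), with 7 at Zbtb46 and 5 each at Flt3 and Itgam. CD8 T cell genes had 2.7 against 1.87 (permutation adjusted p = 0.187), with 8 at Runx3, 5 at Klrd1 and 4 each at Cd8b1 and Crtam. Natural killer cell genes had 2.0 against 1.74 (permutation adjusted p = 0.715), with 6 at Klre1 and 3 each at Eomes and Nfil3. Red cell and platelet genes had 1.75 against 1.47 (permutation adjusted p = 0.634), with 4 each at Gp1bb and Klf1 and 3 at Epor. Ribosome biogenesis genes had 2.67 against 2.2 (permutation adjusted p = 0.148), with 7 at Mak16 and 6 each at Polr1a and Rrp1. Interferon-induced genes had 2.58 against 1.95 (permutation adjusted p = 0.104), with 6 at Isg20 and 4 each at Gbp2, Ifit3, Irf1 and Oas3.

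**Figure D4:**
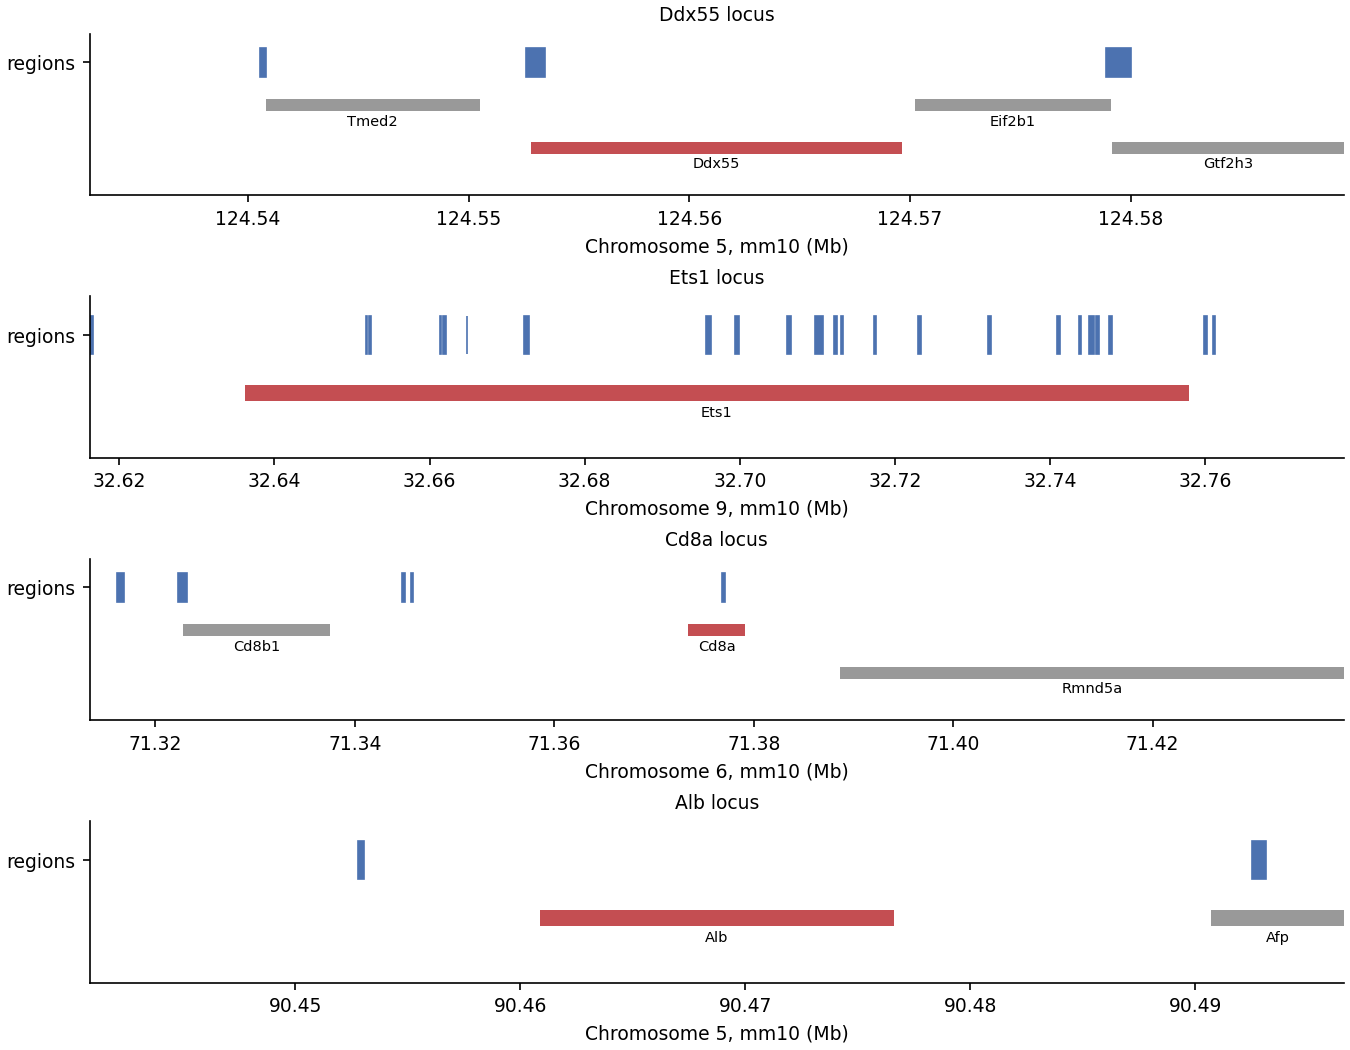
Accessible regions (blue) and protein-coding genes (the titled gene in red, others in grey) along 4 loci, with the position on mm10 in Mb on the horizontal axes. Ddx55 has 1 region, at its lower-coordinate end, Ets1 has 20 regions inside the gene and 0 at its ends, Cd8a has 1 region inside the gene, and Alb has 0 regions in its body.

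Among all protein-coding genes, the 10 with the most regions were mostly long genes. Zfp978, a zinc finger gene in a cluster of related genes on chromosome 4, had 65 regions over 267 kb. Foxp1 had 53 regions, Inpp4b, which encodes a phosphoinositide phosphatase, had 47, and Bach2, a transcription factor of naive lymphocytes, had 34 over 348 kb. The others were Ptprd with 45, Wwox with 41, Lrp1b with 39, Fhit with 38, Pde4d with 35 and Dlg2 with 34, and the shortest of these 6 genes, Wwox, was 913 kb long. Per 100 kb of gene and flanks, Zfp978 had 22.6 regions, Bach2 9.25, Foxp1 8.58, Inpp4b 5.79 and Wwox 4.39. The rest of these genes ranged from 1.71 for Dlg2 to 2.65 for Pde4d. The median protein-coding gene had 2 regions, and 5017 genes (22.9%) had 0.

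Of the 5 widest regions, 1 overlapped a ribosomal RNA pseudogene and 1 overlapped transfer RNA genes. The widest, 5833 bp on chromosome 17 (39842997 to 39848829), overlapped the pseudogene Rn18s-rs5 and the long noncoding RNA gene AY036118. The others were 3493 bp on chromosome Y (140572 to 144064), 3247 bp on chromosome 2 (22587288 to 22590534) over Myo3a, 2872 bp on chromosome 14 (51062892 to 51065763) over 3 transfer RNA genes, and 2852 bp on the scaffold JH584304.1. The use of a list of excluded regions is not known, so these widths are not shown to reflect open chromatin.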

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

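Regions on sequences outside the assembled chromosomes were used in no comparison. The list held 292 regions on 26 unplaced or unlocalized scaffolds (0.453% of all regions). Counted up to the last region of each scaffold, their density was 195.5 per Mb, against 25.7 per Mb on the autosomes. Only scaffolds with a region were counted, and JH584295.1, with 1 region, added 612 bases. The scaffold density is therefore raised by construction. The scaffold JH584304.1 alone had 55 regions, which covered 40.5% of the span between the first and the last of them. No other value met the rules for a closer look, since the list has no values per sample.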

How the results depend on the processing

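The gene lists and some of the alternatives were set before the data were examined. Chosen after seeing the data were windows of 2 kb, the middle of the region for the lists, the whole gene body, the removal of gene ends near another gene, the matched lists in place of Fisher's exact test, and the removal of X and Y, of overlapping list members and of the member with the most regions. No paired analysis was possible because the list has no values per library. The alternatives for knockout against wild type, for motifs, and for windows that need strand were not run. Merging gave 61670 regions and autosomes with X gave 64179; only regions of at least the median width gave 32329, by construction. The share at gene ends was above the placements under all 5 alternatives, from 15.9% to 31.2%. The number of lists called at gene ends stayed within 1.5 times of 10 under all 7 alternatives, with 7 higher in each and 4 lower at 500 bp, 2 lower at 2 kb and 0 lower with the gene body. Of 112 single list results at gene ends, 103 kept their side of the threshold and 0 reversed. B cell genes were no longer called at 2 kb (44.4%), with the gene body (55.6%) or without gene ends near another gene (23.5%). With the gene body, interferon (83.3%), neuronal (50.0%) and liver genes (45.5%) were no longer called and regulatory T cell genes were (100%). Red cell and platelet genes were called at 500 bp (8.33%) and by the middle of the region (16.7%). For region counts, 9 lists were called, 3 without regions at gene ends and 5 (3 higher, 2 lower) without the top member. Without regions at gene ends the lists no longer called were regulatory T (mean 4.33), ribosomal protein (0.725), p53 (1.9), cell cycle (1.29), neuronal (1.83) and liver (0.773). The ratio to matched lists did not fall for regulatory T (1.84 before and after) or p53 (1.59 to 1.82); the upper 95% bound of the matched lists rose from 1.71 to 1.91 and from 1.42 to 1.63 times their mean. Without the top member, which lowers a mean by construction, they were effector helper (3.48, ratio 1.72 to 1.51), regulatory T (5.46, 1.84 to 1.62), p53 (2.9, 1.59 to 1.48) and cell cycle (2.5, 1.41 to 1.29). With the gene body alone, regulatory T (3.83, ratio 1.84 to 1.52) and neuronal genes (1.75, ratio 0.605 to 0.656) were not called, nor was regulatory T (6.27) without overlapping members. Ribosome biogenesis genes were called with wider regions (1.96) and interferon genes with 50 kb flanks (7.25). Apart from the removals of regions, genes or members, the cause of these changes was not tested. Depth is unknown, so a gene without a region is not shown to be closed.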

Other observations

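Families of genes beyond the fixed lists differed in their accessibility. All families and tests in this part were chosen after the values were seen, apart from the test on gene ends in dense windows. Replication histone genes had a region at an end in 58 of 63 cases (92.1%, against 6.65% ± 3.98 over the 100 placements), zinc finger genes named Zfp in 302 of 397 (76.1%) and transfer RNA genes in 184 of 408 (45.1%, against 5.91% ± 1.38). All 8 Gimap genes, GTPases of lymphocyte survival, had one. Olfactory receptor genes had one in 48 of 1110 cases (4.32%, against 9.26% ± 0.813) and vomeronasal receptor genes in 10 of 355 (2.82%, against 10.1% ± 1.64), both below every placement. The T cell receptor segments Trav and Trbv had one in 26.9% and 28.6% of cases, above every placement, and Trbj in 9 of 14. Over the 17 families tested, each of these had a permutation adjusted p = 0.0241. Random placement is a low bar, and most families passed it. All protein-coding genes stood at 52.6% against 11.1% placed, and long noncoding RNA genes, at 24.6%, also passed. The Trav and Trbv shares lay near the latter, so accessibility particular to these segments is not shown. The 3 families that did not pass were Traj with 12 of 60 (20%, permutation adjusted p = 0.0673), keratins with 5 of 53 (9.43%, against 13.9% ± 4.6, permutation adjusted p = 0.547) and the light chain segments Igkv with 9 of 162 (5.56%, permutation adjusted p = 0.574).

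Among genes with at least 10 regions, Gm9758 had 44.4 regions per 100 kb of gene and flanks, Zfp992 39.6, Zdhhc18 24.5, Ubxn11 22.6, Tnfrsf1b 20.2, Tnfsf8 19.9, Il21r 19.6, Il2ra 18.5, Rhoh 17.9, Plcg1 17.1, Panx1 16.8 and Cass4 16.6. These are examples, and no shared function was tested. Genes ranked between them were left out, among them Gm21149 with 44.3, Gm10354 with 40.3, A530032D15Rik with 37.95 and Sfi1 with 27.3.

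Chromosome X had fewer regions than any autosome. Gene number does not account for it: X had 0.909 regions per protein-coding gene, against 1.84 to 4.22 on the 19 autosomes. Fewer reads per site on X, as a single copy would give, may contribute. Narrow regions were missing more than wide ones: the odds ratio of the widest against the narrowest width class for X against autosomes was 2.91 (95% interval 2.37 to 3.56), and X regions had a median width of 428.5 bp against 274.5 to 328.5 bp on autosomes. These widths cannot single out read depth. Of the X regions 36.6% lay at a gene end, against 13.8 to 26.85% on autosomes, and regions at gene ends were wider (median 715 bp). Fewer regions away from gene ends on X, from any cause, could also shift the widths. The regions at Kdm5d, Eif2s3y, Uty and Ddx3y show that at least some cells carried a Y chromosome; the sex of the animals is not in the labels. A biological difference of X chromatin and repeats that block mapping on X were not tested.

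Windows of 100 kb with 16 or more regions numbered 29, with 611 regions, where the median window with a region had 2. Clusters of gene starts do not account for them as a whole, since 12.1% of their regions lay at a gene end (95% exact interval 9.63 to 15.0%), below the 18.5% of all regions. For single windows, where the share ran from 0% to 75% in one with 15 histone genes, this stays open. Reads shared between near-identical copies are a candidate explanation for part of them: uncharacterised gene models made up 24.2% of the genes in these windows and 8.57% elsewhere (odds ratio 3.41, 95% interval 1.94 to 6.01). Some windows lay at the Speer4 and Zfp978 clusters, and others held Ccr7, Prkch, or Id3 with E2f2, for which enhancers of T cell genes remain an untested alternative.

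Ighv segments, which B cells use for antibody heavy chains, had a region at an end in 48 of 183 cases (26.2%), against 5.56% of 162 Igkv segments of the light chain (two-sided Fisher's exact test p = 1.64e-07). The segments of each family lie side by side on a single chromosome and are not independent, so this p-value overstates the evidence. Random placement does not account for the 26.2%, since the highest of 100 placements was 12.02%. That is a low bar, however: the Ighv share lay near the 24.6% of long noncoding RNA genes and the 26.9% of Trav segments. Accessibility particular to Ighv segments, beyond that of such genes, is therefore not shown. B cells among the sorted cells stay open, although the cells had been purified as naive CD4 T cells: 22.2% of the 18 B cell genes had a region at a gene end, against 23.1% of 78 myeloid, red cell and platelet, neuronal and liver genes (odds ratio 0.952, 95% interval 0.279 to 3.26), too few genes to decide. Of the B cell genes, Cd22, Cr2, Ebf1 and Pou2af1 had such a region and the other 14, such as Cd79a, Cd79b and Ms4a1, had none. Reads shared between similar segments and true accessibility of this locus in T cells also stay open and were not tested.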
